A study of Mus musculus with 24 samples.

How the data were processed

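Mature miRNAs of mouse colon mucosa were measured with the NanoString nCounter system, which counts probes bound to single target molecules on a cartridge. Per the labels, the samples are normal mucosa and tumours of mice with the genotype label APC and of mice of the AOM-DSS model. The series' design text names the APC;CpC mouse, in which Cre recombinase removes the tumour suppressor Apc in colon epithelium, and the AOM/DSS mouse, given the carcinogen azoxymethane and the colitis-inducing dextran sulphate sodium. Per the labels' protocols, RNA was isolated from formalin-fixed, paraffin-embedded tissue, whereas the design text describes frozen tissue, and this contradiction could not be settled from the labels. The labels' protocols further state that a core facility prepared the RNA after NanoString's protocol.

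Raw counts of each probe were deposited by the authors for 24 libraries, with 566 mouse miRNA probes, 33 probes for viral miRNAs and 4 mRNA probes (Actb, B2m, Gapdh and Rpl19). Per the file headers, the libraries ran on 3 cartridges: all 11 APC libraries on the first, 7 AOM-DSS normal and 2 AOM-DSS tumour libraries on the second, and 4 AOM-DSS tumour libraries on the third. The headers name the group of each raw count column, and 6 columns matched 1 sample by name. Columns of other series numbered 0. The value table deposited by the authors holds a scaled signal, the raw count times 1 factor per sample with counts of 0 set to 1 (33 values). Dividing by that factor gave whole counts for 100% of its 14376 values within a tolerance of 0.01, and each of its 24 columns then equalled a raw column with 0 set to 1. Library numbers in the text come from this match of recovered counts. The basis of the factor, any background step and the software behind the deposited tables are not given in the sources used here.

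Counts were analysed in R 4.3.3 with edgeR 4.0.16. Because no negative control probes stood in the tables used, the fallback fixed in advance applied: edgeR's filterByExpr (min.count 10, min.total.count 15) kept 563 of the 566 miRNAs and removed 3. TMM factors scaled the libraries, and 1 quasi-likelihood model (robust) was fitted over the 4 groups. Log2 fold changes are given with a standard error, the absolute log2 fold change divided by the square root of the F statistic, and p-values were adjusted after Benjamini and Hochberg over the tested miRNAs of each comparison, with a threshold of 0.05. All adjusted p-values of single miRNAs come from this edgeR test unless another test is named. The comparisons were tumour against normal in each model, the difference between those tumour effects (AOM-DSS minus APC), and AOM-DSS against APC within normal tissue and within tumours. Levels are CPM of the mouse miRNA counts after TMM scaling, which set each library's counts relative to its scaled total. Exact two-sided permutation tests on log2 CPM accompany miR-135b, miR-135a and the mRNA probes. A small offset was added to the counts of the miRNAs and none to those of the mRNA probes. A pseudocount of 1 entered only the log2 of the authors' scaled values.

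The 33 viral probes, for miRNAs of mouse cytomegalovirus and gammaherpesvirus, served as background, set per library at their mean plus 2 SD. This use was chosen after the data were seen. A miRNA at or below this level in every library of a group had only a bound there, given as "at least N-fold": the mean log2 CPM of the brighter group against the mean of the dim group's values, each raised to its library's background where lower. Counts of miRNAs past a fold use fitted folds.

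Named miRNAs were fixed by a rule. It took miR-135a and miR-135b always, and the 10 largest rises and 10 largest falls past the threshold in each tumour comparison whose median raw count exceeded background in a compared group. It took the 5 largest each way in the other comparisons, and up to 4 members of a fixed list with the smallest p. Groups, named-miRNA rule, models, lists and most alternatives were fixed before the data were examined. The 21 lists were the miR-135 family, miRNAs reported raised and reported lowered in colorectal tumours, miR-17-92 and its paralogue clusters, and the miR-183 cluster. They further held the miR-200, let-7, miR-34, miR-29, miR-30, miR-15/16 and miR-181 families, the miR-23/27/24 clusters, the Dlk1-Dio3 imprinted cluster and inflammation-responsive miRNAs. The last were markers of intestinal epithelium, muscle, fibroblast and mesenchyme, endothelium, leukocytes and erythrocytes. The 19 lists with at least 3 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Lists share members, and miRNAs mark cell types only in part. Probes such as miR-106a+mmu-miR-17 count several near-identical miRNAs together. Names and start positions of miRNA genes came from a reference table of assembly GRCm38.p6, and the positions served only to find neighbouring genes.

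Library totals ranged from 47260 to 329346 counts (median 251264). On simulated counts for the real libraries, the test recovered 56.7%, 92.5% and 100% of changes of 1.5-, 2- and 4-fold in the APC comparison, with 4.05% of calls false. The same shares were 62.7%, 94.0% and 98.5% for the AOM-DSS comparison (3.41% false) and 38.8%, 76.1% and 98.5% for the difference between models (4.70% false). They were 50.7%, 98.5% and 98.5% for normal tissue (4.07% false) and 71.6%, 97.0% and 100% for the tumours (4.28% false), each over 563 miRNAs. The simulation held no probe background and no cartridge effect, so recovery may be lower in the real counts, above all for miRNAs near background. In simulated lists for the APC comparison, 3 of 3 shifted lists and 1 of 14 unshifted lists were called. Each simulated miRNA varied on its own, so this does not measure false list calls among miRNAs that vary together.

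Alternatives were DESeq2 1.42.0, limma-voom, upper-quartile scaling, and scaling to the 100 highest miRNAs or to the mRNA probes. Others were no filter, a filter at 2 times the viral background in at least 5 libraries, viral background subtracted, the authors' scaled values with limma, a fit of only the compared groups, a fit without robust weights, replicate numbers as a block, an estimated list correlation, leaving out the shallowest library, and leaving out each library in turn. Chosen after the data were seen were a filter at the viral background, cartridge 3 as a term of the model, cartridges 1 and 2 only, and the recovered counts. Scaling to spike-in probes was not run, since none stood in the tables used. The labels do not say that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical in part. The design text names matched normal tissue, but the labels do not say that equal numbers mark the same mouse. The main fit and the permutation tests were therefore unpaired.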

Results

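The study profiled miRNAs in colon tumours of 2 mouse models and in normal colon mucosa. In the APC model, loss of the tumour suppressor Apc drives tumours, and in the AOM-DSS model tumours follow a carcinogen and chemically induced colitis. The 24 libraries held 6 APC normal, 5 APC tumour, 7 AOM-DSS normal and 6 AOM-DSS tumour samples. Total mouse miRNA counts ranged from 47260 in AOM-DSS normal 7 to 329346, with a median of 251264, and the next shallowest library was APC tumour 1 with 134680. The probe for miR-720, a sequence now regarded as a tRNA fragment, took 25.2% ± 0.705 of the counts in APC normal mucosa (SD, n = 6) and 13.3% ± 5.44 in APC tumours (n = 5), against 21.5% ± 7.35 and 22.2% ± 3.12 in AOM-DSS normal mucosa and tumours (n = 7 and 6). No pair of libraries of a group agreed within sampling noise: the lowest chi-square per degree of freedom was 3.30.

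The series title names miR-135b, a miRNA known to target the Apc transcript, and its level in tumours of both models was the first question. In APC mucosa miR-135b measured 79.8 ± 22.3 CPM (SD, n = 6), at or below the background of the viral probes in all 6 libraries, and in APC tumours 657 ± 95.2 CPM (n = 5), above background in all 5. It rose by 3.07 ± 0.20 on the log2 scale (SE, adjusted p = 2.85e-15), a fitted 8.37-fold and at least 3.97-fold against background. In AOM-DSS mucosa miR-135b measured 72.7 ± 24.5 CPM (n = 7), at background in all 7 libraries, against 299.7 ± 45.7 CPM in tumours (n = 6), above it in all 6. The rise there was 2.07 ± 0.19 on the log2 scale (adjusted p = 3.00e-10), a fitted 4.19-fold and at least 1.58-fold. Every tumour lay above every normal sample in both models. Exact two-sided permutation tests gave p = 0.00216 over 462 arrangements for APC and 0.000583 over 1716 for AOM-DSS, the smallest each design allows (0.00289 and 0.00233 adjusted over 4 tests). Its relative miR-135a, which shares the seed sequence, rose in APC tumours from 178 ± 32.8 to 410 ± 150 CPM, by 1.20 ± 0.20 on the log2 scale (adjusted p = 1.06e-05, exact permutation p = 0.00216). In AOM-DSS tissue miR-135a measured 223 ± 62.0 CPM in normal mucosa and 208.5 ± 47.1 CPM in tumours, a log2 difference of -0.01 ± 0.20 (adjusted p = 0.988, exact permutation p = 0.672). These levels lay near background, which miR-135a exceeded in only 4 of 7 AOM-DSS normal and 3 of 6 AOM-DSS tumour libraries, so a change there may be missed. In APC tissue it exceeded background in 4 of 6 normal libraries and all 5 tumours.

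**Figure D1:**
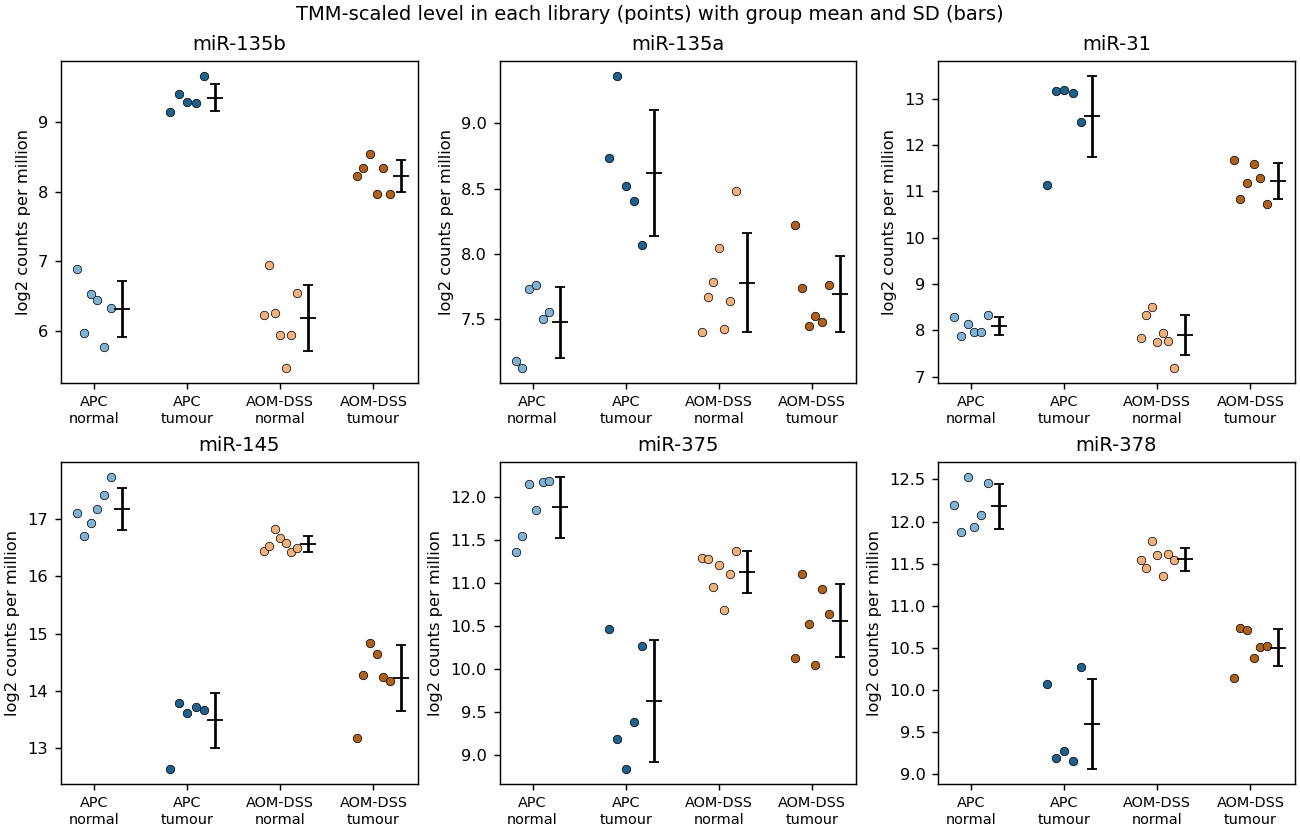
Levels of 6 miRNAs in each library, as log2 TMM-scaled CPM on the vertical axis, for the 4 groups on the horizontal axis; points are libraries, and bars give the group mean and SD. miR-135b lies higher in all 5 APC and all 6 AOM-DSS tumours than in any normal library of its model, while miR-135a measured 223 ± 62.0 CPM in AOM-DSS normal mucosa and 208.5 ± 47.1 CPM in AOM-DSS tumours.

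APC tumours were set against APC normal mucosa to find the miRNAs that change in tumours of this model. miR-31, often raised in colorectal cancer, had the largest fitted rise, 25.99-fold (log2 fold change 4.70 ± 0.29, SE, n = 5 and 6, adjusted p = 5.39e-13), from 273 ± 36.8 to 7082 ± 3070 CPM. The rise of miR-135b has only a bound, so its rank against miR-31 is not measured. miR-205, a miRNA of squamous epithelia, rose 6.11-fold (2.61 ± 0.32), and miR-183 and miR-96, expressed from 1 cluster, rose 3.68-fold (1.88 ± 0.17) and 2.86-fold (1.52 ± 0.15). miR-145 and miR-143, abundant in smooth muscle and stromal cells, fell 12.8-fold (-3.68 ± 0.25) and 12.2-fold (-3.61 ± 0.28), and the muscle miRNA miR-1 fell by 2.66 ± 0.21 on the log2 scale, at least 3.54-fold. miR-378, miR-10a and miR-10b fell 5.82-, 6.17- and 5.19-fold, the last 2 with log2 fold changes of -2.62 and -2.37, or -1.99 and -1.64 without APC normal 3. miR-10b was above background in only 1 of 5 tumours, so the size of its fall depends on background. miR-375, found in islet and enteroendocrine cells, and miR-194, a miRNA of intestinal epithelium, fell 4.46- and 3.25-fold.

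Further rises were at background in all 6 normal libraries: miR-296-5p (at least 1.36-fold), miR-499 (1.08), miR-2133 (1.08), miR-1983 (1.43) and miR-149 (1.52). Of these, miR-296-5p, miR-499 and miR-2133 were above background in only 3 of 5 tumours, and miR-1983 and miR-149 in 4 of 5. The falls of miR-137 (at least 2.60-fold) and miR-133a (2.01), a miRNA of muscle, ended at background in all 5 tumours. Of 563 miRNAs tested, 52 were higher and 71 lower in APC tumours, and 18 of the higher and 30 of the lower had fitted changes of more than 2-fold, including those above with smaller bounds. The split between higher and lower depended on scaling, with 65 and 59 when scaled to the 100 highest miRNAs, and 67.2% of 128 calls higher in the authors' scaled values. All 11 libraries shared 1 cartridge.

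By group, 14 of 22 miRNAs reported raised in colorectal tumours rose and 8 did not pass (camera adjusted p = 2.63e-11), with miR-135b, miR-31, miR-183 and miR-96 first, and 17 rose when adjusted over the list alone. Of 15 reported lowered, 11 fell, led by miR-378, miR-1, miR-194 and miR-145, and 4 did not pass (7.70e-21), with 12 adjusted over the list alone. The miR-183 cluster rose with all 3 members (2.89e-05), miR-182 by 0.99 ± 0.23. Intestinal epithelium markers miR-194, miR-192 (-1.61 ± 0.16) and miR-375 all fell (3.30e-07). Of 5 muscle markers 4 fell (miR-1, miR-145, miR-143 and miR-133a), and miR-133b, at background in all APC tumours and above it in 1 of 6 normal libraries, did not pass (1.30e-12). The share of all counts taken by miR-143 and miR-145 was 18.95% ± 3.95 in normal mucosa and 2.37% ± 0.533 in tumours. These 5 calls held with an estimated correlation (adjusted p = 0.0314, 2.18e-05, 0.0298, 0.00438 and 0.000395 in that order), and list-alone counts of the last 3 equalled those over all miRNAs.

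Another 4 list calls in APC tumours were lost with an estimated correlation. miR-17-92 and its paralogue clusters, raised by Myc in many tumours, had 5 of 11 probes higher and 6 not past the threshold (camera adjusted p = 0.0320, adjusted p = 0.365 with an estimated correlation). The miR-17 probe rose by 0.79 ± 0.14 and miR-25 by 0.73 ± 0.13, and 7 rose adjusted over the list alone. Fibroblast and mesenchyme markers had 2 of 7 higher, miR-99a (1.30 ± 0.17) and miR-199a-3p (0.44 ± 0.13), and 4 adjusted over the list alone (0.0353, adjusted p = 0.183 with an estimated correlation). In the miR-29 family, which targets collagen transcripts, miR-29c (-1.15 ± 0.14) and miR-29b (-0.71 ± 0.13) fell and miR-29a did not pass, with the same count adjusted over the list alone (0.0236, adjusted p = 0.170 with an estimated correlation). In the Dlk1-Dio3 imprinted cluster 16 of 53 fell, 10 of them to background in all tumours, where 8 have no bound above 1-fold, and 37 did not pass. miR-127, at background there, fell at least 1.37-fold, and miR-136 changed by -1.29 ± 0.17. Its list median of -0.089 turned to 0.137 in the authors' scaled values. As many fell when adjusted over the list alone (0.0299, adjusted p = 0.170 with an estimated correlation). Leaving out single libraries ended the miR-17-92 call (adjusted p = 0.0651 without APC normal 4 and 0.0643 without APC normal 5). It also ended the fibroblast call (0.0571 and 0.0650 without APC normal 2 and 4, 0.0549 and 0.0684 without APC tumour 1 and 2) and the Dlk1-Dio3 call (0.0650 without APC normal 4). Other settings ended these calls too. The stricter background filter did so for Dlk1-Dio3 (0.189), fibroblast (0.178) and miR-29 (0.153). The viral background filter (0.104 and 0.0729) and scaling to the mRNA probes (0.0512 and 0.0542) did so for fibroblast and miR-29. A fit of only the compared groups did so for fibroblast (0.0661), miR-29 (0.0631) and miR-17-92 (0.0881).

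The other lists did not pass in APC tumours. In the miR-200 family, miRNAs of epithelial cells, miR-200c rose, miR-200a and miR-200b fell and 2 did not pass (camera adjusted p = 0.588). Among 8 leukocyte markers miR-223 of neutrophils rose by 1.25 ± 0.25, miR-142-5p fell by 0.88 ± 0.14 and 6 did not pass (0.955), and among 3 erythrocyte markers miR-486 fell, to background in all tumours and with no bound above 1-fold (0.244). Of 8 inflammation-responsive miRNAs 3 rose, 1 fell, namely miR-146b (-1.06 ± 0.21), and 4 did not pass (0.588). The let-7 family had 2 higher, 1 lower and 6 not past the threshold (0.955). The miR-34 family, induced by p53, had 1 of 4 higher (miR-34a, 1.18 ± 0.22; 0.107, but 0.0415 with background subtracted), and the miR-30 family 3 of 5 lower (0.107). The miR-15/16 family had 0 of 6 past the threshold (0.955), the miR-23/27/24 clusters 1 higher and 1 lower of 5 (0.955), and the miR-181 family 2 of 3 higher (0.0536, but 0.0470 without APC normal 3, 0.0411 without APC tumour 5, and 0.0230 to 0.0421 with limma-voom, background subtracted or the authors' values). Both miR-135 members rose, and of the 2 endothelial probes miR-126-3p rose (0.43 ± 0.12), in lists too short for the test. Adjusted over the list alone, miR-200 gave 1 higher and 3 lower, leukocytes 2 and 2, erythrocytes 0 and 2 and miR-30 1 and 3, with no change of count in the rest.

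AOM-DSS tumours were set against AOM-DSS normal mucosa to find the miRNAs that change in tumours arising with colitis. miR-31 had the largest fitted rise here as well, 9.63-fold (log2 fold change 3.27 ± 0.26, SE, n = 6 and 7, adjusted p = 3.32e-10), from 244 ± 74.4 to 2447 ± 642.5 CPM. The rises of miRNAs at background in normal mucosa, such as miR-135b and miR-1983, have only a bound and are not ranked against it. The miR-183 cluster rose too, with miR-183 up 2.95-fold (1.56 ± 0.16), miR-182 2.47-fold (1.31 ± 0.21) and miR-96 2.38-fold (1.25 ± 0.14). miR-18a and miR-25, of miR-17-92 and a paralogue cluster, rose 2.19- and 2.13-fold, and miR-18a lost its call when scaled to the mRNA probes (adjusted p = 0.0645). miR-145 and miR-143 fell 4.80-fold (-2.26 ± 0.21) and 4.74-fold (-2.24 ± 0.24), miR-1 3.43-fold (-1.78 ± 0.19) and miR-133a 2.16-fold. The last 2 were above background in only 2 and 1 of 6 tumours, so the size of their fall depends on how background is treated. miR-137, miR-127, miR-365 and miR-378 fell 2.91-, 2.48-, 2.46- and 2.07-fold, although miR-137 and miR-127 were above background in only 3 and 2 of 6 tumours. miR-9, best known from neural tissue, fell by 1.46 ± 0.20 on the log2 scale to background in all 6 tumours, at least 1.603-fold.

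miR-205 rose 2.82-fold and miR-101a fell 2.16-fold, and miR-1983 (at least 1.19-fold) and miR-149 (at least 1.23-fold) rose from background in all 7 normal libraries. In AOM-DSS tumours miR-1983 and miR-149 were above background in only 3 and 4 of 6 libraries. Of 563 miRNAs tested, 48 rose and 48 fell, 11 each with fitted changes of more than 2-fold, including miR-135b, miR-1983, miR-149 and miR-9 with smaller bounds. Scaled to the mRNA probes, 10 rose and 111 fell. Relative to the scaled miRNA total, 3 of those 4 probes were higher in the tumours, Rpl19 by 0.93, Actb by 0.58 and Gapdh by 0.55 on the log2 scale (adjusted exact permutation p = 0.00583, 0.00971 and 0.00583), while none passed in APC tumours. A lower miRNA total in the tumours would give the same values as a higher mRNA level, and these were not told apart. Only cartridge 2 held both groups, with 7 normal and 2 tumour libraries: within cartridges 1 and 2, 58 miRNAs passed (29 higher, 29 lower), and with cartridge 3 as a term 60 passed (32 and 28). Cartridge 3 held only AOM-DSS tumours, so under both settings the AOM-DSS tumour level rested on the same 2 libraries. The settings are therefore not separate checks, and calls may end under them for want of samples. Under these settings miR-101a lost its call (adjusted p = 0.172 and 0.131), as it did with background subtracted (0.384). miR-205 lost its call with the term (0.0648) and when scaled to the mRNA probes (0.0562), whereas miR-135b, miR-31, miR-145 and miR-143 kept theirs.

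In the lists, 15 of 22 miRNAs reported raised in colorectal tumours rose in AOM-DSS tumours and 7 did not pass, with miR-21 at -0.03 ± 0.14 (camera adjusted p = 1.90e-15). Of 15 reported lowered 9 fell, among them miR-1, miR-145, miR-143 and miR-378, and 6 did not pass (3.81e-12), with 11 adjusted over the list alone. miR-17-92 and its paralogue clusters had 8 of 11 probes higher and 3 not past the threshold (2.72e-09), with miR-25 at 1.09 ± 0.12, miR-93 at 0.99 ± 0.12 and the miR-17 probe at 0.99 ± 0.13. All 3 miR-183 cluster members rose (3.19e-07), and 4 of 5 muscle markers fell (1.64e-11), as the share of counts of miR-143 and miR-145 went from 14.7% ± 1.22 to 3.64% ± 1.16. With an estimated correlation these 5 calls held (adjusted p = 0.00907, 0.000346, 0.0156, 0.00905 and 0.000346). The Dlk1-Dio3 imprinted cluster had 14 of 53 lower, 3 of them at background in all tumours with bounds of at most 1.05-fold, miR-127 by a fitted -1.31 ± 0.17 and miR-136 by -0.91 ± 0.15, and 39 not past the threshold (0.00181, adjusted p = 0.0503 with an estimated correlation and 0.134 with the stricter background filter). For AOM-DSS lists with no other count given, the count adjusted over the list alone was the same.

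The remaining AOM-DSS lists did not pass. miR-200c (0.66 ± 0.12) and miR-429 (0.41 ± 0.12) rose and 3 of the miR-200 family did not pass (camera adjusted p = 0.171). Of the intestinal epithelium markers miR-194 fell by 0.37 ± 0.13, and miR-375 (-0.53 ± 0.22) and miR-192 (-0.28 ± 0.14) did not pass (0.164, but 0.0416 scaled to the mRNA probes; 2 fell adjusted over the list alone). Fibroblast and mesenchyme markers had miR-125b-5p (-0.81 ± 0.14) and miR-100 (-0.67 ± 0.15) lower, miR-99a higher (0.49 ± 0.16) and 4 not past the threshold (0.0828, but 0.0349 to 0.0387 with limma-voom, the mRNA probes or the authors' values; 4 lower adjusted over the list alone). Among leukocyte markers miR-223 alone rose, by 0.74 ± 0.22 (0.849), and of inflammation-responsive miRNAs it rose and miR-146b fell by 0.90 ± 0.20 (0.849). In the miR-29 family 2 of 3 fell (0.0665, but 0.0367 without AOM-DSS normal 6) and in the miR-30 family 2 of 5, miR-30a by 0.84 ± 0.13, with 3 adjusted over the list alone (0.0543, but 0.0334 and 0.0392 without AOM-DSS normal 6 and 7, and 0.0421 without AOM-DSS tumour 4). These 2 families passed in 7 and 8 of 18 alternatives (0.0196 to 0.0497 and 0.0209 to 0.0431). In the miR-15/16 family 1 of 6 fell (0.665; 1 higher and 2 lower adjusted over the list alone), the miR-23/27/24 clusters had 1 higher and 1 lower of 5 (0.937) and the miR-181 family 1 of 3 higher (0.665). No member passed among the erythrocyte (0.685), let-7 (0.683) and miR-34 (0.970) lists or of the 2 endothelial probes, and of the miR-135 pair miR-135b rose.

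**Figure D2:**
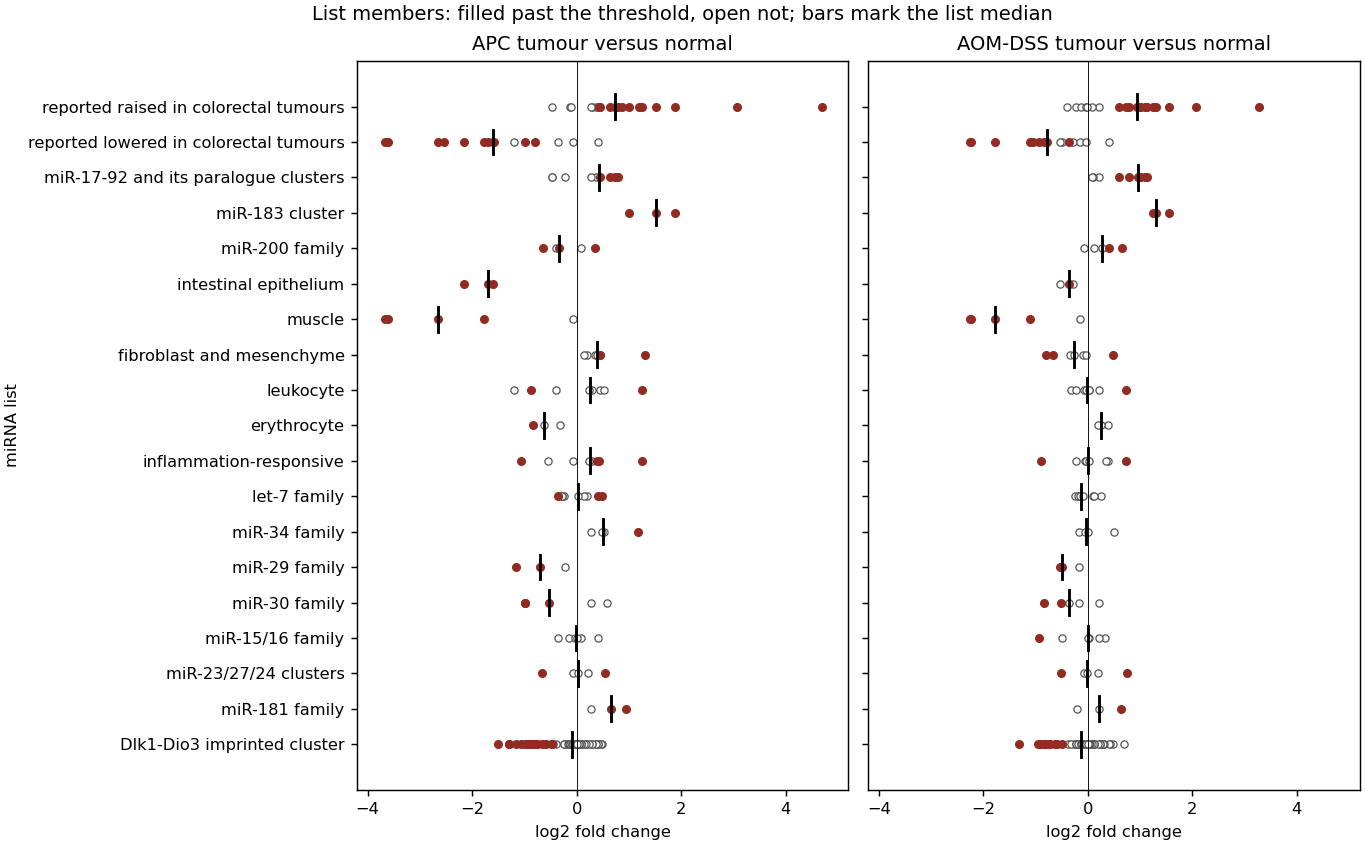
Log2 fold change (tumour versus normal, horizontal axis) of each member of the 19 tested lists (vertical axis), for APC at left and AOM-DSS at right; filled points passed the adjusted p of 0.05, open points did not, and bars mark list medians. Of 5 muscle markers 4 fell in both models, while all 3 intestinal epithelium markers fell in APC tumours and 1 of 3 in AOM-DSS tumours.

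The models were then compared for miRNAs that changed in both. Calls were shared by 60 miRNAs, of which 22 rose and 38 fell in both and 0 moved in opposite directions. Independent lists drawn from all 563 tested miRNAs would share 4.43 and 6.05. That expectation is too low if miRNAs near background are seldom called, so the excess may be smaller. Among the shared miRNAs were miR-31, miR-135b, miR-205, miR-183 and miR-96 on the higher side, and miR-145, miR-143, miR-1, miR-137 and miR-133a on the lower. The fitted change was smaller in AOM-DSS for 46 of the 60. Across the 563 miRNAs, which are not independent replicates, log2 fold changes correlated with Pearson r = 0.639 and Spearman rho = 0.312, and across the 226 above background with 0.802 and 0.680. With cartridge 3 as a term 37 miRNAs were shared.

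**Figure D3:**
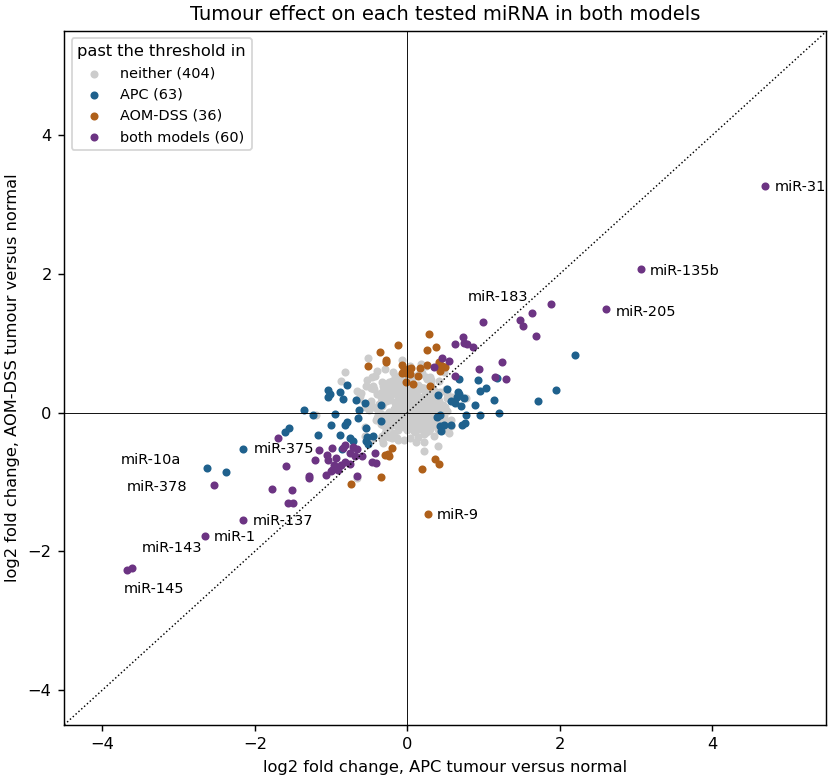
Log2 fold change of the 563 tested miRNAs in APC tumours (horizontal axis) against AOM-DSS tumours (vertical axis), each point 1 miRNA coloured by the comparison it passed; the dotted line marks equal change. The 60 miRNAs past the threshold in both models lie in the quadrants of equal direction, with miR-31 at 4.70 and 3.27 and miR-145 at -3.68 and -2.26.

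Where the tumour effect differed between models was tested as an interaction. miR-375, miR-378 and miR-145 fell further in APC tumours, by 1.63 ± 0.33, 1.49 ± 0.23 and 1.41 ± 0.30 on the log2 scale (adjusted p = 0.00241, 4.65e-05 and 0.00378). miR-2134 (difference 1.40 ± 0.32) and miR-1937c (1.36 ± 0.34) fell in APC tumours, by 1.36 and 1.04 on the log2 scale, and had log2 fold changes of 0.04 and 0.32 in AOM-DSS tumours. miR-9 fell in AOM-DSS tumours and measured 0.27 in APC tumours, a fitted difference of -1.73 ± 0.28 (4.90e-05). Its level in AOM-DSS tumours was at background, so the size of this difference is not measured. miR-31 rose less in AOM-DSS tumours, by -1.43 ± 0.36 (0.0161). The fitted difference of miR-135b was -0.9996 ± 0.288 (0.0262), but it lay at background in all normal libraries of both models, so each rise has only a bound and the difference cannot be sized. miR-135a differed by -1.21 ± 0.28 (0.00479), and miR-1224 and miR-100 by -1.15 ± 0.23 and -1.03 ± 0.21 (0.00171 and 0.00200).

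In all, 38 of 563 miRNAs differed. The log2 change was more positive in AOM-DSS than in APC tumours for 22 and more negative for 16. These counts were 17 and 24 scaled to the 100 highest miRNAs and 2 and 31 scaled to the mRNA probes. In the authors' values 37.1% of 35 were more positive. With cartridge 3 as a term or cartridges 1 and 2 only, 18 and 17 passed, and the calls of miR-135b (adjusted p = 0.114 and 0.132), miR-135a (0.116 and 0.138), miR-31 (0.0986 and 0.0845) and miR-145 (0.0986 and 0.120) ended. The calls of miR-375, miR-378, miR-9, miR-1224, miR-100, miR-2134 and miR-1937c stayed under both. Of these, miR-375, miR-1224 and miR-2134 also differed between the normal mucosa of the models, where model and cartridge cannot be told apart. miR-2134 measured 738 CPM in APC mucosa, against 291 in APC tumours, 302 in AOM-DSS mucosa and 319 in AOM-DSS tumours. miR-1224 measured 551 and 732 CPM in APC mucosa and tumours, and 2123 and 1277 CPM in AOM-DSS mucosa and tumours. The miR-135b difference also lost its call with background subtracted (0.449) and without AOM-DSS normal 2 (0.0754), APC normal 2 (0.0562) or APC normal 5 (0.0570). Scaled to the mRNA probes, the differences of miR-145 (0.179), miR-1937c (0.130) and miR-2134 (0.102) ended, and that of miR-31 did so with limma-voom (0.0674) and with background subtracted (0.503).

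As groups, 9 of 15 miRNAs reported lowered in colorectal tumours had the more positive log2 change in AOM-DSS tumours. They were led by miR-194 (1.33 ± 0.19), miR-378, miR-192 (1.33 ± 0.21) and miR-375, which fell less there than in APC tumours. The change was more negative there for 1 (miR-497, -0.89 ± 0.27), and 5 did not pass (camera adjusted p = 1.54e-07, list alone 10 and 2). All 3 intestinal epithelium markers fell less in AOM-DSS tumours (camera adjusted p = 1.54e-07). Fibroblast and mesenchyme markers had the more negative change there in 4 of 7 (camera adjusted p = 1.37e-06, list alone 6), with miR-100, miR-125b-5p, miR-199a-3p (-0.71 ± 0.18) and miR-99a (-0.81 ± 0.24). These 3 calls held with an estimated correlation (adjusted p = 0.00620, 0.00620 and 0.00721). The muscle call (3 of 5 higher, among them miR-1, which was at background in all APC tumours; list alone 4, 0.00443) was lost with an estimated correlation (adjusted p = 0.0926) with cartridge 3 as a term (0.123), with cartridges 1 and 2 only (0.119) and with background subtracted (0.0667).

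Further list calls lost with an estimated correlation were miR-17-92 and its paralogues (1 of 11, miR-18a, 0.0180, then adjusted p = 0.336), the miR-200 family (0 of 5, list alone 3, 0.0347, then adjusted p = 0.320), erythrocyte markers (miR-486 of 3, at background in APC tumours and AOM-DSS mucosa, list alone 2, 0.0449, then adjusted p = 0.320) and the miR-34 family (0 of 4, 0.0449, then adjusted p = 0.0926). Scaled to the mRNA probes, the list medians of miR-17-92 and miR-200 turned to -0.21 and -0.08. Scaling to the mRNA probes, background subtraction and both background filters ended the calls of miR-17-92 (0.0625 to 0.232) and miR-200 (0.0773 to 0.227). Erythrocyte markers and miR-34 lost theirs in 7 and 9 of 15 alternatives. Leaving out single libraries also ended these 4 calls: miR-17-92 without APC normal 1 (adjusted p = 0.0766), and miR-200 without AOM-DSS normal 5 or 6, AOM-DSS tumour 3, APC normal 1 or APC tumour 1 or 5 (0.0550 to 0.0723). The call of erythrocyte markers ended without AOM-DSS normal 1, 2, 3, 6 or 7, AOM-DSS tumour 1 or 3, APC normal 1 or 3 or APC tumour 1 or 5 (0.0570 to 0.119), and that of miR-34 without AOM-DSS normal 1, 2, 6 or 7, AOM-DSS tumour 1 or 3, APC normal 1 or 6 or APC tumour 2, 4 or 5 (0.0510 to 0.0723). Not past the threshold were the lists reported raised (1 higher and 3 lower of 22, 0.554), miR-183 (0 of 3, 0.681), leukocyte (0 of 8, list alone 1, 0.671), and inflammation-responsive (0 of 8, 0.312). Nor did let-7 (let-7e lower of 9, 0.580), miR-29 (miR-29c higher of 3, 0.312), miR-30 (0 of 5, 0.967), miR-15/16 (miR-497 lower of 6, 0.652), miR-23/27/24 (0 of 5, 0.926), miR-181 (0 of 3, list alone 1, 0.0918) or Dlk1-Dio3 (0 of 53, 0.967). Of the miR-135 pair both were lower, and of the endothelial probes miR-126-3p was lower (-0.63 ± 0.17; list alone 2).

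Normal mucosa of the models was compared as a baseline. miR-1224 was 3.87-fold higher in AOM-DSS than in APC mucosa (log2 fold change 1.95 ± 0.16, SE, n = 7 and 6, adjusted p = 1.18e-11), followed by miR-2132 (2.58-fold), miR-762 (2.04, above background in only 2 of 6 APC libraries), miR-125a-3p (1.77) and miR-376b (1.71). miR-2134 was 2.38-fold lower (-1.25 ± 0.21), and the epithelial miRNAs miR-141, miR-375 and miR-200a were 1.72-, 1.71- and 1.61-fold lower, with miR-804 1.81-fold lower. miR-135b and miR-135a did not pass, at -0.14 ± 0.23 and 0.23 ± 0.20 (adjusted p = 0.830 and 0.640). In all 19 miRNAs passed, 9 higher and 10 lower (7 and 15 with upper-quartile scaling, 3 and 1 scaled to the mRNA probes, 83.3% of 24 higher in the authors' values). Each model's normal libraries ran on a cartridge of their own, and a cartridge effect cannot be excluded. Fits that left out a library used the recovered counts, which with all libraries gave 13 calls, all among the 19. Against these 13, the count was 12, 9, 10 and 9 without AOM-DSS normal 1, 2, 4 and 5, and 9 and 11 without APC normal 3 and 4. Part of the distance from the 19 therefore came with the recovered counts. Single calls that ended in these fits may have ended for the same reason. The call of miR-375 ended without any normal library but APC normal 2 (adjusted p = 0.0542 to 0.133). That of miR-804 ended without AOM-DSS normal 1, 2, 3, 4, 5 or 7 or APC normal 3 or 4 (0.0679 to 0.206), and that of miR-376b without AOM-DSS normal 2 or 6 or APC normal 2, 4 or 5 (0.0580 to 0.0838). Scaled to the mRNA probes, the calls of miR-141 (0.175), miR-200a (0.178), miR-125a-3p (0.178), miR-762 (0.178), miR-376b (0.175), miR-375 (0.147) and miR-804 (0.178) ended. Those of miR-762 (0.174) and miR-376b (0.269) also ended with background subtracted, and that of miR-376b with limma-voom (0.0506). In all, miR-375 and miR-804 lost their calls in 7 and 9 of 15 alternatives.

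Tumours of the models were compared in the same way. miR-150, a lymphocyte miRNA, was 4.06-fold higher in AOM-DSS tumours (log2 fold change 2.02 ± 0.46, SE, n = 6 and 5, adjusted p = 0.00663), and miR-192 and miR-194 of intestinal epithelium were 2.16-fold (1.11 ± 0.16) and 1.96-fold (0.97 ± 0.14) higher. miR-451, abundant in erythrocytes, was 1.97-fold higher, and miR-376b, at background in all 5 APC tumours, gave a log2 fold change of 1.12 ± 0.26 and no bound above 1-fold. miR-205 and miR-31 were 2.90-fold lower in AOM-DSS tumours (-1.54 ± 0.31 and -1.53 ± 0.25), and miR-135b and miR-135a were lower by -1.14 ± 0.17 and -0.98 ± 0.20. miR-135a was above background in only 3 of 6 AOM-DSS tumours, so the size of its difference depends on background. miR-708, above background in only 1 of 6 AOM-DSS tumours, had a fitted 2.41-fold lower level. miR-9 was at background in all AOM-DSS tumours and at least 1.43-fold lower, and miR-499, at background there too, had a log2 fold change of -1.79 ± 0.36 and no bound above 1-fold.

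Between the tumours, 49 miRNAs passed, 27 higher and 22 lower in AOM-DSS (17 and 25 scaled to the 100 highest miRNAs, 2 and 63 scaled to the mRNA probes, 22 and 11 with background subtracted, 43.2% of 37 higher in the authors' values). With cartridge 3 as a term 16 passed and with cartridges 1 and 2 only 10, and neither removes the confounding of model with cartridge 1. The differences of miR-150 (adjusted p = 0.489 and 0.548), miR-135a (0.165 and 0.161), miR-376b (0.0599 and 0.0813) and miR-499 (0.0699 and 0.0878) ended under these settings, whereas those of miR-135b, miR-192, miR-205 and miR-708 kept their calls. With background subtracted, the calls of miR-135b (0.247) and miR-31 (0.0581) ended. The count was 31, 28 and 28 without APC tumour 2, 3 and 4. The difference of miR-451 ended without AOM-DSS tumour 1 or 3 or APC tumour 1, 3, 4 or 5 (0.0560 to 0.0815), with limma-voom (0.0524), when scaled to the 100 highest miRNAs (0.0809) and in the authors' values (0.0964). Scaled to the mRNA probes, the differences of miR-194 (0.0720), miR-376b (0.152) and miR-451 (0.172) ended.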

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

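Chosen only after the result was seen were the comparison of miR-192, miR-194 and miR-375 with the miR-200 family, the test of cartridge on the normal tissue, and the settings with cartridge 3 as a term and with cartridges 1 and 2 only.

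The muscle markers miR-1, miR-133a, miR-143 and miR-145 fell in tumours of both models, with list medians of -2.66 in APC (-1.82 with miR-1 and miR-133a, at background in all APC tumours, at their bound) and -1.78 in AOM-DSS tumours on the log2 scale. The tables argue against a scaling set by a few abundant miRNAs, since the weakest list median under 3 other scalings and a background filter was -1.70, and against cartridge, since the AOM-DSS median within cartridge 2 was -2.01 and all APC libraries shared 1 cartridge. Less muscle tissue in the tumour samples may account for part of the fall, but the test of it does not decide this. Over the 13 normal libraries, miR-1 deviated from its group mean together with miR-143 and miR-145 (Pearson r = 0.742, permutation p = 0.0144, Spearman rho = 0.709, permutation p = 0.0178, both 0.0178 when adjusted). With normal libraries only, it shows that these miRNAs varied together there and does not measure muscle in the tumours. That relation rested on few samples, with r = 0.510 (p = 0.115) without the 2 farthest libraries, r = 0.923 within APC normal mucosa (exact permutation p = 0.0167, n = 6) and r = 0.164 within AOM-DSS normal mucosa (exact permutation p = 0.7625, n = 7). A fall within the cells of the tumour itself stays open and was not tested.

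miR-192, miR-194 and miR-375, markers of intestinal epithelium, fell more in APC than in AOM-DSS tumours, by a median difference of 1.33 on the log2 scale. The tables argue against cartridge as the cause, since all APC libraries shared 1 cartridge and the median was 1.36 with cartridges 1 and 2 only (lowest of the 3, 1.25), and against the shallow library AOM-DSS normal 7, since it was 1.29 without it (lowest 1.28). The mean of the 3 changed by -1.67 relative to the mean of the miR-200 family in APC tumours (exact permutation p = 0.00216, the smallest possible), and by -0.68 in AOM-DSS tumours. This argues against a loss of epithelial cells as a whole in APC tumours only if miR-200 levels per epithelial cell stayed the same. In APC tumours miR-200c rose while miR-200a and miR-200b fell, so that condition is unsure. A biological difference between the tumours of the models stays open and was not tested.

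Normal mucosa of the models differed in 19 miRNAs, by a median of 0.77 on the log2 scale, although each model ran on its own cartridge. A cartridge effect common to all tissue predicts the same shift between the tumours, which lay on the same sides, and their median shift in that direction was 0.116 (95% bootstrap interval -0.06 to 0.25), with 13 of 19 in the same direction and a median of 0.047 with cartridges 1 and 2 only. The 19 were picked for their shift between normal tissues, so a smaller shift between the tumours is partly built in. The interval resamples these miRNAs and not libraries. This test therefore does not decide whether such an effect is the whole cause. The tables argue against the shallow library, since 14 of the 19 remained called without it. A difference between the mice of the models or in how their tissue was taken stays open and untested. A cartridge effect, on all tissue or on normal tissue alone, cannot be excluded by this test.

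Of 100 splits of the libraries into groups of the real sizes, the real one included, 1 gave as many called miRNAs in each comparison. Chance is therefore an unlikely source of these counts, though so few splits cannot rule it out entirely. The counts were 123 in APC tumours (highest other split 100), 96 in AOM-DSS tumours (68), 38 for the difference between models (4), 19 in normal tissue (4), 49 between tumours (27) and 60 in both models (0). For lists, 7 of 100 splits gave as many called lists as the 9 in APC tumours (highest other 11) and 27 of 100 as many as the 6 in AOM-DSS tumours (9), so that chance cannot be excluded for those list counts. The median of the other splits was 2 called lists in APC tumours and 2 in AOM-DSS tumours. For the difference between models, 4 of 100 splits reached the 8 lists called (highest other 10, median 1).

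Among 134 groups of values tested for a sample far from the others, 10 had one, where chance alone gives about 1 in 20, or 6.7. AOM-DSS normal 7, with a total of 47260 counts against at least 258878 in the others, stood apart in log2 CPM for miR-137 (9.75), miR-365 (10.60) and miR-376b (9.66). APC tumour 1, with a total of 134680 counts, was low in miR-145 (12.63). APC normal 2 was low in miR-125a-3p (7.67), APC tumour 5 high in miR-194 (13.40), AOM-DSS tumour 3 high in miR-18a (9.28) and AOM-DSS normal 6 high in miR-2134 (9.10).

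The tumour effect differed between models in the interaction test for 15 named miRNAs, given as AOM-DSS minus APC on the log2 scale. The difference was positive for miR-375 (1.63), miR-378 (1.49), miR-145 (1.41), miR-2134 (1.40), miR-1937c (1.36), miR-143 (1.36), miR-194 (1.33), miR-1 (0.88, from a level at background in all APC tumours) and miR-18a (0.85). It was negative for miR-9 (-1.73, from a level at background in all AOM-DSS tumours), miR-31 (-1.43), miR-135a (-1.21), miR-1224 (-1.15), miR-100 (-1.03) and miR-135b (-0.9996, from normal levels at background in both models). For miR-1, miR-9 and miR-135b these are fitted values, and the size of the difference is not measured.

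The mRNA probes enter the comparisons of miRNAs only as an alternative scaling. Relative to the scaled miRNA total, they were higher in AOM-DSS tumours than in AOM-DSS mucosa for Rpl19 (0.93 on the log2 scale), Actb (0.58) and Gapdh (0.55), with adjusted exact permutation p = 0.00583, 0.00971 and 0.00583. These values cannot tell a higher mRNA level from a lower miRNA total. B2m measured -0.08 there (0.629), and in APC tumours none of the 4 passed (adjusted exact permutation p from 0.114 for Gapdh to 0.563 for Actb).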

How the results depend on the processing

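The filter at the viral background, both cartridge settings and the recovered counts were chosen only after the data were seen. Over 19 alternatives and 24 fits that left out 1 library each, no named miRNA past the threshold changed direction, but the medians of 3 called lists changed sign. These were Dlk1-Dio3 in APC tumours (0.137 in the authors' values), and miR-17-92 (-0.21) and miR-200 (-0.076) for the difference between models, scaled to the mRNA probes. Of 77 results of named miRNAs, 53 kept their side of the threshold throughout, though 2 of them, neither past it, changed sign (miR-135a in AOM-DSS tumours, miR-135b between normal tissues). The 53 were 21 of 21 in APC tumours, 18 of 21 in AOM-DSS tumours, 5 of 11 for the difference between models, 5 of 12 between normal tissues and 4 of 12 between tumours. Of 57 list results 41 kept their side, and the medians of 19 of these, not past the threshold, changed sign. Counts of called miRNAs moved by over 1.5 times as follows, with the cause not tested except where fewer samples or fewer miRNAs entered. With background subtracted they were 62 in AOM-DSS tumours, 25 for the difference between models and 10 between normal tissues. Scaled to the mRNA probes they were 74 in APC tumours and 4 between normal tissues, and filtered at the viral or 2 times that background 35 and 36 between normal tissues. With cartridge 3 as a term they were 60 in AOM-DSS tumours, 18 for the difference, 16 between tumours and 37 in both models, and with cartridges 1 and 2 only, where fewer libraries entered, 58, 17 and 10. Under both cartridge settings the AOM-DSS tumour level rested on the same 2 libraries, so the settings are not separate checks. List calls went from 6 to 10 in AOM-DSS tumours scaled to the mRNA probes and from 9 to 5 in APC tumours with an estimated correlation. For the difference between models, list calls went from 8 to 3 with background subtracted and with an estimated correlation, and to 4 scaled to the mRNA probes and under either background filter, where fewer miRNAs were tested.

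With the recovered counts of all libraries, 13 miRNAs passed between normal tissues, against 19 in the main fit. On those counts, leaving out 1 library gave 9 to 17 calls there, lowest without AOM-DSS normal 2 or 5 or APC normal 3. The count was 12 without AOM-DSS normal 1, 10 without AOM-DSS normal 4 and 11 without APC normal 4. Between tumours, leaving out 1 library gave 28 to 53, with 31 without APC tumour 2 and 28 without APC tumour 3 or 4. For lists of the difference between models it gave 4 to 8, with 5 without AOM-DSS normal 6, AOM-DSS tumour 3 or APC tumour 5 and 4 without APC normal 1. Without the shallow library AOM-DSS normal 7, the counts were 122 in APC tumours, 98 in AOM-DSS tumours, 43 for the difference, 16 between normal tissues and 51 between tumours. The median log2 fold change of all miRNAs moved by over 0.1 with the mRNA probes (by -0.47 in AOM-DSS tumours, -0.52 for the difference, -0.46 between tumours) and with background subtracted (-0.50 in APC tumours, 0.41 for the difference, 0.35 between tumours). It also did so in the authors' values (0.23 in APC tumours, -0.15 for the difference, 0.12 between normal tissues) and with no filter (-0.11 in AOM-DSS tumours).

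The design text names matched normal tissue, and replicate numbers are shared between normal and tumour samples of a model. Over all tested miRNAs, same-numbered samples did not deviate together. The correlations of their deviations ran from -0.32 to -0.01 over 5 APC pairs, with 0 best with their own number. Over 6 AOM-DSS pairs they ran from -0.09 to 0.11, with 1 best. Many of these miRNAs lay near background, so the check cannot show that the samples were unpaired. With the replicate number as a block the counts were 100 in APC tumours, 90 in AOM-DSS tumours and 34 for the difference, and 5 lists were called for the difference. The block changed the calls of miR-135b for the difference (adjusted p = 0.109), of miR-17-92 in APC tumours (0.0539) and of the miR-200 (0.0634), erythrocyte (0.0794) and miR-34 (0.0634) lists for the difference, and of no other named result. Depth limits weak miRNAs: 226 of 563 lay above the viral background in at least 5 libraries.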

Other observations

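The count of neighbouring pairs that moved in the same direction and the test on miRNAs above background were chosen only after the result was seen, and the restriction to pairs outside the Dlk1-Dio3 cluster was not part of the planned test. Genes of many miRNAs lie close together and can share a primary transcript, which gave a hypothesis: miRNAs of neighbouring genes may change alike in tumours. For 468 of 563 tested miRNAs matched to 1 gene, 700 pairs lay within 10000 bases and carried different numbers. The planned test gave no sign of such a likeness. The median absolute difference of log2 fold change was 0.408 in APC tumours and 0.329 in AOM-DSS tumours, against 0.372 and 0.313 in random pairs of like expression (permutation p = 0.851 and 0.709). The planned reading, that such p-values would speak against the hypothesis, was too strict, because a p above the threshold does not exclude likeness. Restricted to miRNAs above background, the median difference over 60 pairs was 0.457 in APC and 0.331 in AOM-DSS tumours, against 0.709 and 0.577 in random pairs (permutation p = 0.0308 and 0.0039, 0.0616 and 0.0204 adjusted over 8 tests). Outside the Dlk1-Dio3 cluster, 26 such pairs gave permutation p = 0.0051 and 0.0628 (0.0204 and 0.100 adjusted). Over all 238 pairs outside that cluster the permutation p was 0.0137 and 0.0882 (0.0365 and 0.118 adjusted). Among pairs with both members called, 43 moved in the same direction and 0 in opposite directions in APC tumours (8.74 and 8.52 in random pairs), and 38 and 0 in AOM-DSS tumours (5.74 and 5.61), with permutation p = 0.0001 for both, the smallest possible. Outside the cluster it was 10 and 0 in each model (permutation p = 0.0018 and 0.001). These counts are consistent with shared transcription of called neighbours, while the planned test leaves it open for the rest.

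The viral probes measured 6.503 ± 0.191 log2 CPM in APC mucosa and 6.66 ± 0.14 in APC tumours (SD, adjusted exact permutation p = 0.303, n = 6 and 5), and 6.59 ± 0.20 and 6.58 ± 0.17 in AOM-DSS mucosa and tumours (0.892, n = 7 and 6). Between the 2 AOM-DSS tumours of cartridge 2 and the 4 of cartridge 3, edgeR called 0 miRNAs, and 46 had an unadjusted p under the threshold.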
